A study of Mus musculus with 76 samples.

How the data were processed

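RNA of C57BL/6J mice was measured in 5 settings: 16 uteri at the window of implantation, 16 unstimulated and 16 stimulated horns, 15 placentas and 13 deciduas, 76 libraries in all. Per the labels' protocols, polyadenylated RNA was fragmented and copied from random hexamers into directional or non-directional libraries, and which of these was used is not given in the sources used here. Without stated strand, genes that overlap on opposite strands could not be told apart. The submitters' processing notes name CASAVA 1.8, HISAT2 2.0.5, DESeq2 1.20.0 and the builds GRCm38 and mm10, and the counting program is not given in the sources used here.

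The deposited tables held, per the file headers, a whole-number read count per gene and library, with gene symbol, biotype, length and coordinates. The authors' 3 count tables covered 54532 genes, and 103 symbols occurred on more than 1 gene. The authors also deposited 26 tables of their own comparisons, with a log2 fold change, a p-value and an adjusted p-value per gene. Values of these tables are printed as the authors'. The same counts repeated in the comparison tables differed from the count tables in 0 values. A further 394 columns of per-sample values (FPKM and repeats of the counts) were not used. Samples were mapped to groups by their titles.

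Everything else was computed from the deposited counts. For each of 6 fits (the 5 settings, and both horns jointly) genes were filtered with edgeR's filterByExpr and scaled with TMM. Groups were compared with the quasi-likelihood test with robust dispersion (edgeR 4.0.16, R 4.3.3). All groups of a setting shared 1 estimate of spread. In all 35 comparisons were made: 26 between 2 groups and 9 interactions or differences of the horn response. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes of genes with 3 counts or fewer in a group are given as ratios with exact 95% counting intervals, which cover counting error only. A floor of 3 counts over the group bounded genes at 0, and of 137 list medians tested, not all described, 9 moved by over 0.1 with such genes at the bound (or, for differences, without them), by at most 0.771.

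Of 39 gene lists of cell types, pathways and hormone responses 38 were tested. Camera (limma 3.58.1) was used on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Adjusted p-values are over the lists of a comparison. The same test with the correlation estimated from the data was an alternative. A list score is the mean log2 CPM of its genes in a library. Lists were fixed from textbook markers, and members can be expressed by several cell types.

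The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison between 2 groups, up to 5 protein-coding genes with the highest and 5 with the lowest log2 fold change among called genes with a mean log2 CPM of at least 2 and no overlap between libraries, clone names left out. It added up to 4 called members with the smallest p of each list that passed or held at least 3 called genes. It further took Ar, Esr1 and Pgr in every fit, Prl8a2 in the uterine fits, and up to 5 called genes per interaction.

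Alternatives were DESeq2 1.42.0 in place of edgeR, size factors in place of TMM, no filter on low counts, only the 2 groups compared, the replicate number or mouse as a block, each library left out in turn, and a trophoblast score as covariate in decidua. Chosen after the data were seen were a correction for gene length and leaving out libraries high in squamous markers at the window of implantation, leaving out PNA normal-diet mouse 1 or control high-fat mouse 2 in the horns, a yolk sac score as covariate in placenta, and leaving out deciduas that stood apart. Y-linked counts were at most 5 in a library, so a covariate for fetal sex was not fitted.

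Per the labels both horns came from the same mouse. Deviations of a mouse's horns from their group means correlated, across genes, between -0.737 and 0.480 with a median of 0.111, over 0.1 in 8 of 16 mice. In the other fits replicates of different groups shared only a number.

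Libraries held 15194222 to 35986762 counts. The fit was tested on simulated data with real means and library sizes, for PNA on normal diet or horns. There 100 genes changed 4-fold and 100 2-fold. At the window of implantation (17376 genes) edgeR recovered 93 and 41 with 10 false calls, in unstimulated horns (17138) 70 and 26 with 3, and in stimulated horns (17076) 63 and 32 with 6. Placenta (16120) gave 94 and 55 with 8, and decidua (15825) 57 and 6 with 1. Horns of controls on normal diet (18327) gave 71 and 39 with 1. Real recovery can be lower: placental Ccl3 rose over 4-fold, uncalled. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.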

Results

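Polyadenylated RNA was sequenced from 76 mouse libraries to ask how prenatal androgen and a high-fat diet altered the uterus before and during pregnancy. Exposed females were daughters of dams given 250 µg of the androgen dihydrotestosterone daily between E16.5 and E18.5 of gestation (prenatal androgenization, PNA). PNA and control females ate a normal or a high-fat diet. In the first experiment, uteri were taken after ovariectomy and estradiol and progesterone injections setting up the window of implantation, with 4 mice per group. In the next, hormone-treated ovariectomized females had 25 µl of oil placed in 1 uterine horn, and both horns of 4 mice per group were profiled. Oil is an artificial stimulus for decidualization, the change of uterine stroma into the secretory tissue that receives an embryo. In the last, mated females were killed at E16.5 and the decidua was parted from the placenta. This gave 4 placentas per group (3 in controls on normal diet) and 13 deciduas, 4 from PNA mice on normal diet and 3 from each other group. Levels are counts scaled by library size (CPM), as mean ± SD over the libraries of a group. Log2 fold changes carry their SE, and adjusted p-values of genes come from edgeR's quasi-likelihood test and of gene lists from limma's camera test. In lists, brackets give the members on the stated side of 0, the median log2 fold change and the camera adjusted p. Genes given as examples fell outside the naming rule and were chosen after their values were seen. Per the labels each library of a group is a separate mouse. Gene p-values measure spread between libraries, with horns unpaired unless blocked. Preset camera p-values compare a list with other genes, taking genes as nearly independent. Counts adjusted over a list alone ignore that it was picked from 38.

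At the window of implantation, PNA against control mice on the high-fat diet asked what androgen exposure did on that diet (n = 4 per group). Fbxo32, a muscle ubiquitin ligase gene, fell to 57.1 ± 12.1 against 148 ± 23.1 CPM (log2 fold change -1.37 ± 0.18, adjusted p = 0.0337, lower in 4 of 4 libraries). Ar, the androgen receptor gene, stood at 49.3 ± 17.9 against 122 ± 6.18 CPM (-1.31 ± 0.41, adjusted p = 0.0998, lower in 4 of 4; DESeq2 adjusted p = 0.0243). Esr1, the estrogen receptor alpha gene, stood at 287 ± 76.5 against 415 ± 29.6 CPM (-0.53 ± 0.22, adjusted p = 0.133), and Pgr, the progesterone receptor gene, at 142 ± 48.2 against 195 ± 27.2 CPM (-0.46 ± 0.30, adjusted p = 0.295). Collagen and extracellular matrix genes stood lower as a list, 26 of 29 below 0 with a median log2 fold change of -1.08 (camera adjusted p = 6.67e-06, and adjusted p = 0.959 with an estimated correlation). None of the matrix genes was called among all genes, and 2 fell adjusted over the list alone. An example was Lox, an enzyme gene that crosslinks collagen, at 44.1 ± 14.9 against 109.9 ± 16.1 CPM (-1.32 ± 0.36, adjusted p = 0.0839).

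Endothelial (13 of 15 below 0, -0.68, camera adjusted p = 0.00365), complement (16 of 20, -0.69, 0.00365) and interferon response lists (21 of 28, -0.38, 0.00561) stood lower as well. An estimated correlation gave adjusted p = 0.858, adjusted p = 0.564 and adjusted p = 0.959. No member was called among all genes, and adjusted over the list alone 5 complement, 2 interferon and 0 endothelial genes fell. An example was C1ra, a complement protease gene, at 61.7 ± 18.5 against 114 ± 9.40 CPM (-0.88 ± 0.21, adjusted p = 0.0745). In the same libraries levels moved with gene length. The slope of a library's deviation from the mean log2 CPM of all libraries on log2 gene length was between -0.31 and -0.09 in PNA high-fat mice 2, 3 and 4. It was 0.10 to 0.11 in PNA high-fat mouse 1 and the control high-fat libraries. EdgeR called 1 of 17537 genes, with 5316 at unadjusted p under 0.05, and DESeq2 called 2190. The edgeR count was 5138 without PNA high-fat mouse 1, where Ar (-1.60), Esr1 (-0.68), Lox (-1.51) and C1ra (-1.07) were called, and 562 with the length trend removed, where Esr1 was at 0.05. It was 0 with the replicate number as a block, with only the 2 groups fitted, or without any 1 of mice 2, 3 and 4 of either group, while Fbxo32 stayed between -1.42 and -1.29. The collagen median was -1.71 without PNA mouse 1, and the interferon median -0.25 without PNA mouse 4. With the length trend removed Lox (-1.22) and C1ra (-0.96, adjusted p = 0.0461) were called.

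**Figure D1:**
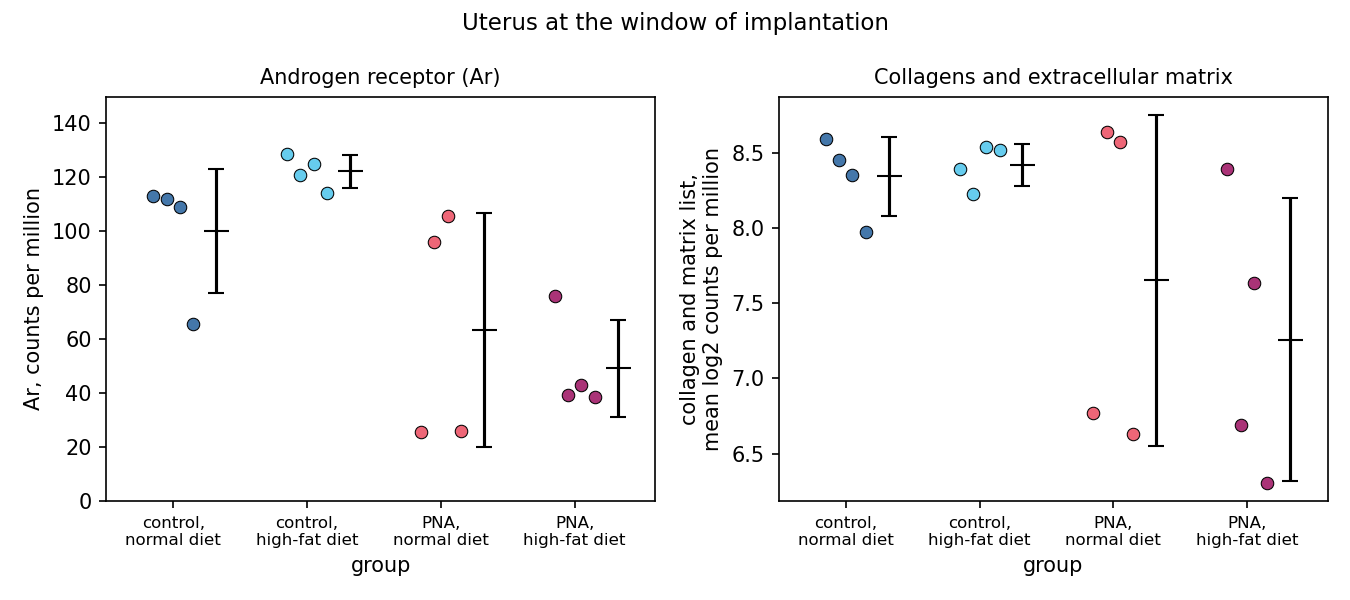
Ar in CPM and the collagen and extracellular matrix list score (mean log2 CPM) at the window of implantation, with 1 point per library and bars for the mean ± SD of 4 mice. Ar was 49.3 ± 17.9 CPM in PNA mice and 122 ± 6.18 CPM in controls on high-fat diet.

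In PNA mice on the normal diet at the same stage (n = 4 per group), the comparison asked what androgen exposure did without the diet. Uterine epithelium markers stood lower, 17 of 17 below 0 with a median of -0.77 (camera adjusted p = 0.000531), with 0 called and 4 lower adjusted over the list alone. This list and the next 4 had adjusted p = 0.858 with an estimated correlation. An example was Muc1, a cell surface mucin gene, at 28.6 ± 9.25 against 55.6 ± 14.1 CPM (-0.96 ± 0.25, adjusted p = 0.291). Cholesterol synthesis (23 of 25, -0.57, 0.000893), complement (15 of 20, -0.45, 0.0154), collagen (23 of 29, -0.40, 0.0105) and adipocyte lists (15 of 15, -3.49, 0.0381) stood lower too. No member of these lists was called among all genes, and 10 adipocyte, 7 complement, 0 cholesterol and 0 collagen genes fell adjusted over the list alone. Lpl, a lipoprotein lipase gene abundant in fat, was at 8.97 ± 5.78 against 98.8 ± 124 CPM (-3.46 ± 0.89, adjusted p = 0.291), and Ar at 63.4 ± 43.4 against 100 ± 23.0 CPM (-0.66 ± 0.41, adjusted p = 0.380). The squamous epithelium markers averaged 7.30 log2 CPM in control normal-diet mouse 3 and 4.65 in PNA normal-diet mouse 4. Without these libraries the cholesterol, collagen and adipocyte lists lost their calls at medians of -0.03, -0.06 and -0.94. The collagen call was also lost without PNA mouse 1 (-0.11) or 4 (-0.10), the cholesterol call without control mouse 3 (-0.06), and the adipocyte call without PNA mouse 2 (-3.63) or 3 (-3.82), control mouse 1 (-3.76) or 3 (-0.61), or with only the 2 groups fitted (-3.47). EdgeR called 0 of 17537 genes, with 2881 at unadjusted p under 0.05, and DESeq2 called 122. EdgeR called 1 gene without control normal-diet mouse 4. Collagen medians were -0.81 and -0.71 without PNA mouse 2 or 3. The slope on gene length was -0.27 in PNA mice 1 and 4 and 0.07 to 0.10 in the other 6 libraries, and with that trend removed the 5 lists stayed called, collagen at -0.31 (adjusted p = 0.00701).

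The diet comparisons at the window of implantation asked what the high-fat diet did on each background (n = 4 per group). In controls the cell cycle list stood lower on high-fat diet, 30 of 30 genes below 0 with a median of -0.95, as did cholesterol synthesis (25 of 25, -0.57) and epithelium markers (16 of 17, -0.55), at camera adjusted p-values of 1.63e-06, 1.63e-06 and 0.000212. Each had adjusted p = 0.575 with an estimated correlation. An example was Msmo1, a sterol oxidase gene of cholesterol synthesis, at 22.4 ± 1.51 against 45.8 ± 42.0 CPM (-1.03 ± 0.41, adjusted p = 0.974). In PNA mice the cell cycle list again lay below 0 in 30 of 30 genes (-1.37, camera adjusted p = 1.12e-20, and adjusted p = 0.923 with an estimated correlation). The interaction, which tested whether the PNA effect differed between diets, was positive for epithelium (16 of 17, 0.78, 3.79e-05) and cholesterol genes (24 of 25, 0.60, 1.09e-06), each at adjusted p = 0.493 with an estimated correlation. None of the genes in these lists was called, among all genes or adjusted over the list alone. By edgeR 0 genes were called for diet in controls (880 at unadjusted p under 0.05, 1 by DESeq2), 0 for diet in PNA mice (597 and 14) and 0 in the interaction (500 and 0). Without the libraries high in squamous markers, or control normal-diet mouse 3 alone, cholesterol in controls lost its call (-0.09), and the epithelium call in controls was lost without control normal-diet mouse 4 (-0.31). Without control normal-diet mouse 3 the cell cycle median in controls was -0.48 and the cholesterol interaction 0.20, the latter 0.94 without PNA normal-diet mouse 3.

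Stimulated against unstimulated horns of control mice on normal diet asked what the oil stimulus did to an unexposed uterus (n = 4 mice, both horns of each). Prolactin-family gene Prl8a2, a marker of mouse decidual cells, rose to 13041 ± 20974 against 1.08 ± 1.74 CPM (13.53 ± 4.23, adjusted p = 0.0185). Cyp11a1, the enzyme gene that starts steroid synthesis, rose to 878 ± 695 against 0.200 ± 0.135 CPM (12.02 ± 3.35, adjusted p = 0.0117). Tdo2, a tryptophan dioxygenase gene of decidua, rose to 2067 ± 641 against 0.604 ± 0.657 CPM (11.69 ± 3.17, adjusted p = 0.0107). Of 28 decidual markers 23 rose and 3 fell (24 and 3 adjusted over the list alone) with a median of 3.87. Among them were the gap junction gene Gja1 (4.52 ± 1.19, 0.00985), the thyroid hormone deiodinase gene Dio3 (4.93 ± 1.16, 0.00800) and the signalling gene Wnt6 (5.49 ± 1.29, 0.00800). Of 30 cell cycle genes 24 rose (25 adjusted over the list alone; median 2.64), with Rrm2, which makes deoxynucleotides, at 4455 ± 2396 against 27.9 ± 9.58 CPM and the mitotic kinase gene Aurka at 24.8 ± 7.43 against 3.06 ± 1.34 CPM. Collagen genes rose in 15 of 29 (15 adjusted over the list alone), including Col4a1 of basement membrane (2.38 ± 0.54, 0.00789) and Lox (3.56 ± 0.81, 0.00789). Interferon response genes rose in 16 of 28 (20 adjusted over the list alone), with Isg15 at 2.55 ± 0.65 (0.00926) and Irf7 at 2.09 ± 0.53 (0.00908). Hypoxia and glycolysis genes rose in 11 and fell in 1 of 25 (13 and 1 adjusted over the list alone), with Pgk1, a glycolytic kinase gene, at 1.74 ± 0.46 (0.00969).

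In the same horns uterine natural killer genes rose in 9 of 21 (10 adjusted over the list alone). Granzyme genes led them: Gzmf rose to 205 ± 138 against 0.326 ± 0.460 CPM (0.00789). Gzmd had 24708 counts in stimulated and 2 in unstimulated libraries, a ratio of 13965 with a 95% counting interval of 3865.5 to 115320. Of 11 junctional zone and giant cell trophoblast genes 5 rose (8 adjusted over the list alone; median 4.59, and 4.35 with genes near 0 counts at their bound). They were Tpbpa, Tpbpb and Plac1, trophoblast genes, and Gjb3 and Pcdh12, a connexin and a cadherin gene of other cells too. Epithelium markers fell in 11 of 17 (14 adjusted over the list alone; median -2.24), with the keratin gene Krt18 at -2.76 ± 0.68 (0.00866) and the adhesion gene Cdh1 at -1.78 ± 0.53 (0.0149). Adipocyte genes fell in 10 of 17 (13 adjusted over the list alone), with the lipase genes Lpl at -3.55 ± 1.01 (0.0128) and Lipe at -1.68 ± 0.36 (0.00789). Oviduct and ciliated cell genes fell in 7 of 7 (7 adjusted over the list alone), with the cilia regulator Foxj1 at -6.91 ± 1.62 (0.00800). The hedgehog ligand gene Ihh (-6.09 ± 1.40, 0.00789) and the homeobox gene Msx1 (-3.83 ± 0.82, 0.00789), both of the receptive uterus, fell, as did Gstm7 (0.00789), a glutathione transferase gene, and Cdh16 (0.00901), an epithelial cadherin gene. Ar (-1.34 ± 0.41, 0.0173) and Esr1 (-1.06 ± 0.32, 0.0171) fell and Pgr (0.94 ± 0.30, 0.0215) rose. All genes named here moved the same way in 4 of 4 mice. The lists had camera adjusted p-values between 7.48e-09 (cell cycle) and 0.0162 (oviduct), and they had adjusted p = 0.869 with an estimated correlation, or adjusted p = 0.919 for the interferon and natural killer lists. EdgeR called 6694 of 18614 genes, 3373 higher and 3321 lower, and DESeq2 called 7469. The count was 3585 without the stimulated library of mouse 3, where the junctional zone list lost its call (3.03), and with mice as a replicate block Prl8a2 (13.23, adjusted p = 0.0670) and Foxj1 (-4.00, adjusted p = 0.0695) lost theirs. The calls of Ar (-1.05), Esr1 (-0.80) and Cdh1 (-1.44) were lost without stimulated mouse 3, and of Pgr (0.82), Foxj1 (-1.79) and Prl8a2 (13.33) without unstimulated mouse 2. With only the 2 groups fitted the natural killer (1.39), junctional zone (2.26) and oviduct lists (-2.98) lost their calls, as did the natural killer list without stimulated mouse 4 (0.29) and the oviduct list without unstimulated mouse 2 (-1.79).

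**Figure D2:**
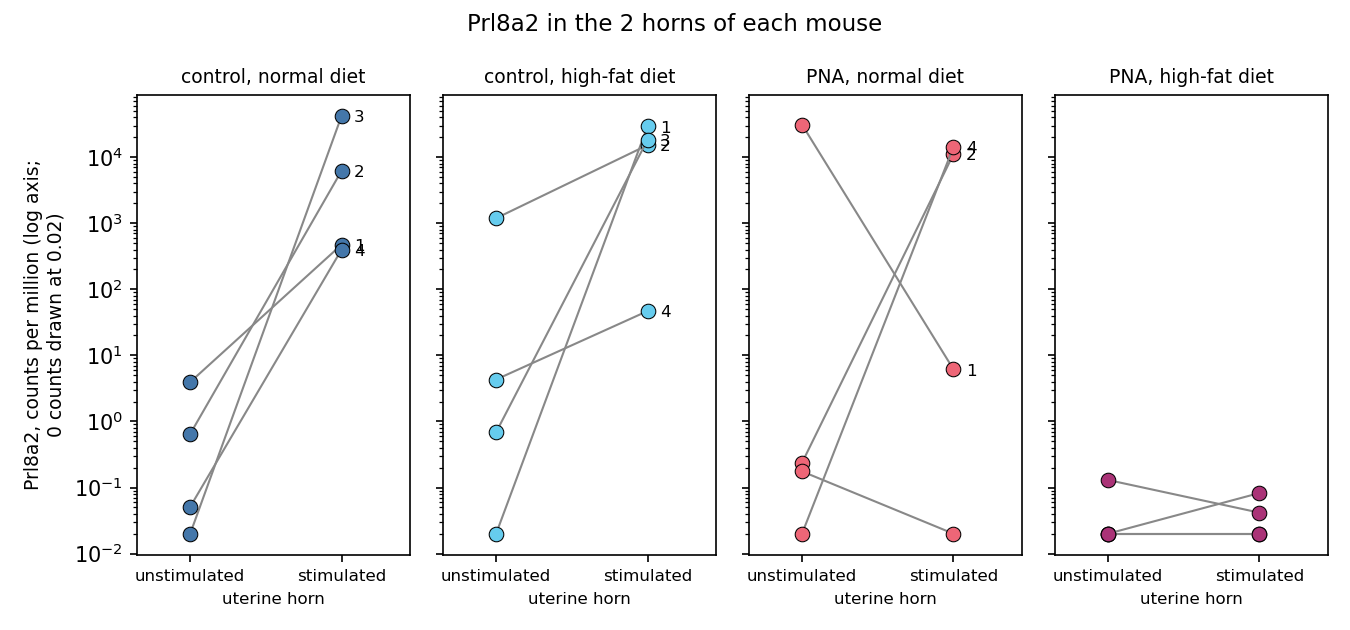
Prl8a2 in CPM on a log axis for every mouse, with the unstimulated and stimulated horn of each mouse joined by a line and 0 drawn at 0.02. Stimulated horns of PNA mice on high-fat diet had 0.03 ± 0.04 CPM and those of controls on high-fat diet 15730 ± 12079 CPM (SD, n = 4).

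The same comparison in controls on high-fat diet (n = 4 mice) again gave lower epithelium and higher decidual transcripts in the stimulated horn. Epithelium markers fell in 12 of 17 (13 adjusted over the list alone; median -3.20, camera adjusted p = 1.20e-05), including Cdh1 (-2.18 ± 0.53, 0.00788). This list and the next 6 had adjusted p = 0.958 with an estimated correlation. Decidual markers rose in 7 and fell in 2 of 28 (8 and 2 adjusted over the list alone; median 2.13, 3.40e-05), and Prl8a2 stood at 17277 ± 13336 against 277 ± 552 CPM (5.96 ± 3.15, adjusted p = 0.144). The unstimulated horn of control high-fat mouse 2 held 1191 CPM of Prl8a2, and without that mouse Prl8a2 was called at 13.45 (adjusted p = 0.0246). MHC class II genes fell in 8 of 14 (11 adjusted over the list alone; -1.75, 0.00221) and unfolded protein response genes rose in 12 of 23 (12 adjusted over the list alone; 0.70, 0.000535). Endothelial genes rose in 5 of 15 (6 adjusted over the list alone; 0.68, 0.0127). Estrogen-responsive genes fell in 8 of 21 (8 lower and 1 higher adjusted over the list alone; -1.32, 0.0434), with complement C3 at 257 ± 52.7 against 5274 ± 3072 CPM (0.00482) and the arginine deiminase gene Padi4 at 2.28 ± 1.69 against 72.3 ± 41.3 CPM (0.00482). The cell cycle list stood higher in 29 of 30 (0.65, 0.000676) with 0 called, also adjusted over the list alone. Without the unstimulated library of mouse 2 the decidual median was 4.11 and the cell cycle median 2.05, and the latter was 0.36, 0.32 and 0.38 without unstimulated mouse 3 or 4 or stimulated mouse 4.

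In this response Alox5, a leukotriene synthesis gene (5.60 ± 1.69, 0.0178), the protease inhibitor gene Tfpi2 (3.89 ± 1.35, 0.0318) and the cadherin gene Cdh3 (3.76 ± 1.24, 0.0262) led the genes that rose. The kallikrein gene Klk1 (-6.24 ± 1.48, 0.00703), the uroplakin-like gene Upk3bl (-5.64 ± 1.05, 0.00445) and Cdh16 (-5.55 ± 1.36, 0.00797) led those that fell, and Msx1 fell too (-3.30 ± 0.80, 0.00760). Ar (-1.49 ± 0.41, 0.0127) and Esr1 (-1.28 ± 0.33, 0.00944) fell and Pgr (1.04 ± 0.30, 0.0156) rose, and each gene named moved its way in 4 of 4 mice. EdgeR called 5770 of 18614 genes, 2505 higher and 3265 lower, and DESeq2 called 6891. The count was 2389, 2802 or 2970 without unstimulated mouse 1, 3 or 4 and 3331 or 3389 without stimulated mouse 2 or 3. It was 2951 with only these 2 groups fitted, where Pgr (1.02, adjusted p = 0.0777) and Cdh3 (3.76, adjusted p = 0.0515) lost their calls. With 1 library left out calls were lost for Alox5 (5.24 to 5.37, without unstimulated mouse 1, 3 or 4), Tfpi2 (3.56 to 3.80, those or stimulated mouse 2 or 3), Cdh3 (3.37 to 3.53, those of Alox5 or stimulated mouse 1), Pgr (0.79 and 0.95, unstimulated mouse 1 or 3) and Ar (-1.17, unstimulated mouse 4). The estrogen-responsive list lost its call with mice as a replicate block (-1.37), without mouse 2 (-1.26) or without stimulated mouse 4 (-0.96), and the endothelial list without stimulated mouse 4 (0.65). The responses of the control groups, which shared no library, called 3945 genes in the same direction, 1754 higher against 454 for independent lists and 2191 lower against 583, and 1 gene in opposite directions.

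Horns of PNA mice asked whether exposed uteri answered the stimulus (n = 4 per group). On normal diet, mesothelium markers stood higher in stimulated horns (10 of 10, 2.26, camera adjusted p = 6.60e-08, and adjusted p = 0.240 with an estimated correlation), as did erythroid (9 of 10, 1.99, 2.30e-12, and adjusted p = 0.0715) and collagen genes (26 of 29, 0.64, 2.21e-08, and adjusted p = 0.423). In all, 8 mesothelium, 5 erythroid and 0 collagen genes rose adjusted over the list alone. Decidual markers had a median of 0.05 (16 of 28 above 0, 0.00537, and adjusted p = 0.822). That call was lost with only the 2 groups fitted (0.08), or at medians of -0.45 to -0.17 without either library of mouse 2 or 4 or the unstimulated library of mouse 3. Without unstimulated mouse 1, which held 31043 CPM of Prl8a2, the decidual median was 2.74. On high-fat diet, adipocyte genes stood higher (17 of 17, 2.85, 4.64e-12, and adjusted p = 0.243 with an estimated correlation), with endothelial genes (14 of 15, 0.42, 1.83e-07, and adjusted p = 0.332), and none of them was called, also adjusted over the list alone. Prl8a2 was at 0 to 0.08 CPM in the 4 stimulated horns there. EdgeR called 0 genes on normal diet (505 at unadjusted p under 0.05, 5 by DESeq2) and 0 on high-fat diet (317 and 30). Exchanging mouse 1's horns gave 3384 on normal diet, so that 0 cannot show no response. Without stimulated mouse 3 the medians were 0.80 (mesothelium), 0.41 (collagen) and 0.34 (decidual) on normal diet and 1.47 (adipocyte) on high-fat diet. On normal diet collagen was at 1.05 without unstimulated and decidual genes at 0.38 without stimulated mouse 1.

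The difference of the horn responses tested whether the stimulus acted unlike in PNA and control mice. On normal diet it was negative for cell cycle (30 of 30, -2.42, camera adjusted p = 1.33e-08), decidual (25 of 28, -3.54, or -3.39 without genes near 0 counts, 6.81e-05) and interferon genes (27 of 28, -1.89, 2.93e-06) and positive for mesothelium (9 of 10, 3.20, 0.000508), each at adjusted p = 0.866 with an estimated correlation. The counts adjusted over the list alone were 19 decidual, 17 interferon and 0 cell cycle genes negative and 8 mesothelium genes positive. On high-fat diet it was negative for decidual (24 of 28, -1.82, or -1.68 without genes near 0 counts, 0.000171). It was positive for epithelium (16 of 17, 2.76, 0.000171), MHC class II (14 of 14, 2.04, 0.000171), smooth muscle (14 of 15, 2.76, 0.00518) and adipocyte genes (16 of 17, 4.68, 0.00444), each at adjusted p = 0.982 with an estimated correlation. Of these, 10 epithelium, 11 MHC class II, 10 smooth muscle, 12 adipocyte and 0 decidual genes passed adjusted over the list alone, and the adipocyte list lost its call without the stimulated library of PNA mouse 3 (3.41). The difference for Ar was 1.55 ± 0.57 (adjusted p = 0.114) on high-fat and 1.62 ± 0.57 (0.121) on normal diet. EdgeR called 0 genes on normal diet (5055 at unadjusted p under 0.05, 1310 by DESeq2) and 0 on high-fat diet (5089 and 1489). On normal diet it called 1235 without the stimulated library of PNA mouse 4 (Ar among them, 1.85) and 1 without the unstimulated library of control mouse 1, and on high-fat diet 4254 without the unstimulated library of control mouse 2 (Ar among them, 1.76). On normal diet the decidual median was -0.80 without the unstimulated library of PNA mouse 1 and -0.46 without both its horns, where the cell cycle median was -1.25. Interferon was at -0.96 without stimulated control mouse 4 and mesothelium at 1.73 without stimulated PNA mouse 3. On high-fat diet the decidual median was -3.75 without unstimulated control mouse 2.

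The diet differences of the response asked whether the high-fat diet altered it. In controls they were negative for uterine natural killer (21 of 21, -1.72, or -1.48 without genes near 0 counts, camera adjusted p = 2.15e-11, and adjusted p = 0.466 with an estimated correlation) and cell cycle genes (30 of 30, -2.01, 4.96e-07, and adjusted p = 0.952). They were positive for mesothelium (8 of 10, 2.14, 6.16e-08, and adjusted p = 0.441). There 4 natural killer genes and 0 of the others passed adjusted over the list alone. In PNA mice they were negative for erythroid (9 of 10, -1.64, or -2.31 without genes near 0 counts, 1.08e-11, and adjusted p = 0.0905). No gene of it passed adjusted over the list alone. Of all genes edgeR called 0 in controls (588 at unadjusted p under 0.05, 35 by DESeq2) and 0 in PNA mice (236 and 28). Without control high-fat mouse 2 the cell cycle call was lost (-0.22), as without only its unstimulated library (-0.33). Natural killer genes were at -1.11 without stimulated control normal-diet mouse 4.

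**Figure D3:**
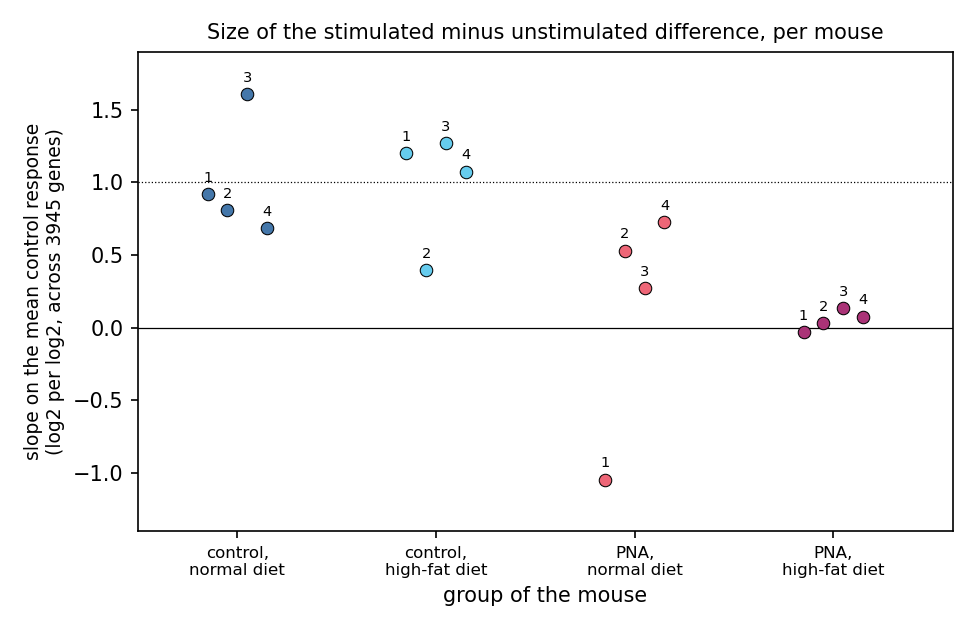
Slope of each mouse's horn response (log2 CPM stimulated minus unstimulated) on the mean of the other control mice. The 3945 genes used were called alike in both control groups, which may favour controls. Control mice lay between 0.40 and 1.61, PNA mice on high-fat diet between -0.03 and 0.13, and PNA normal-diet mice 1 to 4 at -1.05, 0.53, 0.27 and 0.73.

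Within the stimulated horn, PNA against control mice on high-fat diet asked how exposed and unexposed uteri stood after the stimulus (n = 4 per group). Decidual markers fell in 21 and rose in 3 of 28 (23 and 3 adjusted over the list alone; median -4.01, camera adjusted p = 1.69e-05). This and every other list of the comparison had adjusted p = 0.936 with an estimated correlation. Prl8a2 had 3 counts in the PNA and 1328405 in the control libraries, a level 407610 times lower with a 95% counting interval of 139480 to 1976600. Gja1 was at 97.6 ± 14.3 against 3159 ± 636 CPM (-5.02 ± 0.78, 0.00144) and Dio3 at 33.8 ± 15.7 against 662 ± 239.5 CPM (-4.29 ± 0.67, 0.00144). The signalling gene Wnt4 was at 11.4 ± 3.66 against 183 ± 21.4 CPM (-4.01 ± 0.75, 0.00208) and Cyp11a1 at 0.143 ± 0.192 against 1303 ± 778 CPM (0.00221). Cell cycle genes fell in 18 of 30 (26 adjusted over the list alone; -1.76, 1.14e-05), with Rrm2 at -7.32 ± 1.5 (0.00284), the S-phase regulator E2f1 at -1.77 ± 0.45 (0.00777) and the mitotic gene Birc5 at -2.70 ± 0.69 (0.00808). Epithelium markers rose in 13 of 17 (14 adjusted over the list alone; 3.34, 0.000126), with Cdh1 at 2.46 ± 0.52 (0.00317), Krt18 at 3.55 ± 0.75 (0.00333) and Krt7 at 4.58 ± 1.07 (0.00517). MHC class II genes rose in 9 of 14 (10 adjusted over the list alone; 1.9, 0.00627), with H2-Ab1 at 175 ± 60.7 against 33.1 ± 7.63 CPM (0.00843) and H2-Aa at 139 ± 56.1 against 28.7 ± 8.03 CPM (0.00850).

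Interferon genes fell in 12 of 28 (12 adjusted over the list alone; -1.04, 0.00627), with Ifit2 at -2.41 ± 0.45 (0.00208) and Isg15 at -2.55 ± 0.62 (0.00603), both induced by interferon. This list and those below had adjusted p = 0.936 with an estimated correlation. Endothelial genes fell in 9 and rose in 1 of 15 (9 and 1 adjusted over the list alone; -0.84, 0.0135), with the vessel adhesion genes Cdh5 at -3.02 ± 0.67 (0.00423) and Pecam1 at -1.86 ± 0.46 (0.00703). Estrogen-responsive genes rose in 9 and fell in 2 of 21 (9 and 2 adjusted over the list alone; 1.57, 0.0426), with C3 at 5469 ± 552 against 235 ± 47.1 CPM (0.00269) and Padi4 at 5.54 ± 1.05 (0.00212). Unfolded protein response genes fell in 8 of 23 (8 adjusted over the list alone; -0.55, 0.0127), with Edem1, which acts in protein quality control, at -1.74 ± 0.44 (0.00741). Junctional zone and giant cell trophoblast genes fell in 8 of 11 (8 adjusted over the list alone; -5.23, and -5.01 with genes near 0 counts at their bound, 0.0426). They were Prl8a9, Prl2c5, Prl7a2, Tpbpa, Tpbpb, Plac1, Gjb3 and Pcdh12, the last a cadherin gene also of endothelium at -1.53 ± 0.29 (0.00220). Adipocyte genes rose in 7 of 16 (10 adjusted over the list alone) with a camera adjusted p of 0.0797, which was 0.0152 with no filter on low counts.

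Ar (93.6 ± 33.1 against 26.5 ± 6.97 CPM, 1.82 ± 0.46, 0.00736) and Esr1 (393 ± 35.5 against 145 ± 46.1 CPM, 1.44 ± 0.32, 0.00424) were higher and Pgr (198 ± 56.0 against 400.4 ± 36.8 CPM, -1.02 ± 0.20, 0.00253) lower in PNA horns on high-fat diet. Msx1 rose (4.10 ± 0.78, 0.00217), the activin antagonist gene Fst (-3.76 ± 0.74, 0.00236) and the stromal transcription factor gene Wt1 (-3.02 ± 0.45, 0.00139) fell, and Klk1 (6.69 ± 1.64, 0.00634) and Upk3bl (5.82 ± 1.04, 0.00188) led the genes that rose. Every gene named in this comparison was on its side of the control mean in 4 of 4 PNA libraries, with no overlap between the groups. EdgeR called 7615 of 17288 genes, 3737 higher and 3878 lower, and DESeq2 called 8873. The replicate number as a block ended the calls of the estrogen-responsive (1.25) and junctional zone lists (-5.48), the latter lost also with only the 2 groups fitted (-1.67) or without control mouse 1 (-5.50). The estrogen-responsive call was lost without control mouse 4 (1.19) or PNA mouse 1 (1.05), and the adipocyte list passed without control mouse 2 (3.74) or PNA mouse 1 (4.18) or 4 (4.21).

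On normal diet the stimulated horns of PNA mice (n = 4 per group) asked the same without the diet. Cell cycle (30 of 30 below 0, -1.09, camera adjusted p = 1.74e-08), decidual (25 of 28, -1.0, 0.000275) and interferon genes (26 of 28, -0.95, 0.00549) stood lower. These and the next 4 lists had adjusted p = 0.825 with an estimated correlation. MHC class II (13 of 14, 1.30, 2.18e-05), epithelium (15 of 17, 1.59, 0.000149), mesothelium (9 of 10, 2.46, 0.000452) and oviduct markers (6 of 7, 1.84, 0.00564) stood higher. The counts adjusted over the list alone were 8 mesothelium and 6 oviduct genes higher, 1 decidual gene lower and 0 in the other lists. Prl8a2 was at 6343 ± 7435 against 12311 ± 20073 CPM (-0.96 ± 2.09, adjusted p = 0.804), with 11090 and 14274 CPM in PNA mice 2 and 4 and 6.16 and 0 CPM in mice 1 and 3; the library of mouse 1 labelled unstimulated held 31043 CPM, and without mouse 1 Prl8a2 was at -0.54 (adjusted p = 0.924). Ar stood at 1.32 ± 0.45 (adjusted p = 0.139), Esr1 at 0.63 ± 0.32 (0.258) and Pgr at -0.61 ± 0.20 (0.129). EdgeR called 0 of 17288 genes, with 3765 at unadjusted p under 0.05, and DESeq2 called 1369. The edgeR count was 1506 without PNA normal-diet mouse 4, where Ar was called (1.57), and the interferon call was lost without control normal-diet mouse 4 (-0.02). Prl8a2 turned to 1.38 without control normal-diet mouse 3 and to 0.26 with the replicate number as a block. Without PNA mouse 4 the cell cycle and decidual medians were -1.68 and -1.60, and the decidual median was -0.40 without control mouse 3 and the mesothelium median 1.24 without PNA mouse 3.

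For diet in the stimulated horn (n = 4 per group), controls on high-fat diet stood lower in erythroid (8 of 9, -1.42, camera adjusted p = 4.39e-12, and adjusted p = 0.349 with an estimated correlation), uterine natural killer (21 of 21, -1.36, 8.68e-10, and adjusted p = 0.585) and inflammatory cytokine genes (23 of 25, -1.09, 0.000206, and adjusted p = 0.617). There 2 erythroid genes fell adjusted over the list alone. The cytokine call was lost without control normal-diet mouse 4 (0.00). In PNA mice the diet went with lower decidual (24 of 28, -2.71, 6.61e-06), erythroid (8 of 9, -2.07, 3.49e-06) and interferon genes (28 of 28, -0.69, 0.00101), each at adjusted p = 0.790 with an estimated correlation. By list, 15 decidual and 7 erythroid genes fell and 1 decidual gene rose adjusted over the list alone. The interaction was negative for decidual (24 of 28, -2.75, or -2.39 without genes near 0 counts, 0.000234, 11 adjusted over the list alone), at adjusted p = 0.998 with an estimated correlation. No gene passed by diet with edgeR: 0 in controls (371 at unadjusted p under 0.05, 1 by DESeq2) and 0 in PNA mice (2196 and 624), with 0 in the interaction (1902 and 200). In PNA mice edgeR called 479 genes without PNA normal-diet mouse 1 and 114 without mouse 3, and the interaction 1 gene without mouse 1. In controls the erythroid median was -2.16 without control high-fat mouse 4, the natural killer median -0.82 without control normal-diet mouse 4 and -2.22 without control high-fat mouse 2, and in PNA mice interferon was at -0.40 without PNA normal-diet mouse 4.

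The unstimulated horns showed how hormone-treated uteri differed with no stimulus (n = 4 per group). On normal diet, PNA horns stood higher in decidual markers (23 of 26, 2.67, camera adjusted p = 0.000593) and interferon genes (27 of 28, 0.86, 7.43e-09) and lower in adipocyte (15 of 16, -2.88, 2.20e-14) and oviduct genes (7 of 7, -3.20, 0.00427). They had adjusted p = 0.715 with an estimated correlation, or adjusted p = 0.359 for adipocyte genes, and 7 decidual genes rose and 9 adipocyte and 6 oviduct genes fell adjusted over the list alone. The decidual score was 8.59 log2 CPM in PNA normal-diet mouse 1, and without it the decidual median was 0.02. The oviduct call was lost without control normal-diet mouse 2 (-0.15). On high-fat diet, PNA horns stood lower in interferon (28 of 28, -0.92, 9.73e-10), endothelial (14 of 15, -0.74, 2.95e-07) and mitochondrially encoded transcripts (13 of 13, -0.50, 2.25e-05) and higher in mesothelium markers (9 of 10, 1.99, 3.83e-09). An estimated correlation gave adjusted p = 0.853, adjusted p = 0.752, adjusted p = 0.853 and adjusted p = 0.529. In these lists 6 mesothelium genes rose, 1 endothelial gene fell and 0 others passed adjusted over the list alone. An example was Rsad2, an antiviral gene induced by interferon, at 12.2 ± 2.57 against 23.4 ± 1.27 CPM (-0.94 ± 0.32, adjusted p = 0.677). EdgeR called 0 of 17343 genes on normal diet (1221 at unadjusted p under 0.05, 10 by DESeq2) and 0 on high-fat diet (1276 and 19). Interferon medians were 1.52 and 0.39 on normal diet without control mouse 1 or PNA mouse 4. On high-fat diet interferon and endothelial medians were -0.57 and -0.45 without control mouse 2, and the mitochondrial median -0.33 without PNA mouse 3.

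By diet, unstimulated control horns stood higher on high-fat diet in cell cycle (30 of 30, 2.03, camera adjusted p = 6.11e-09) genes and lower in adipocyte (16 of 16, -2.25, 2.87e-12) and mesothelium genes (9 of 10, -2.09, 2.06e-11). The first had adjusted p = 0.741 and the others adjusted p = 0.278 with an estimated correlation, and adjusted over the list alone 6 mesothelium and no cell cycle or adipocyte genes passed. The cell cycle call was lost without control high-fat mouse 2 (0.34). Mitochondrially encoded transcripts stood higher too (13 of 13, 0.47, 1.77e-07, and adjusted p = 0.735). In PNA mice interferon (28 of 28, -1.24, 1.69e-15), T cell (11 of 11, -1.89, 0.000502), endothelial (14 of 15, -0.62, 6.30e-08) and decidual genes (22 of 26, -2.39, 0.0117) stood lower on high-fat diet. Interferon and endothelial genes had adjusted p = 0.594 and the other lists adjusted p = 0.777 with an estimated correlation, and 5 T cell, 2 interferon, 1 endothelial and 0 decidual genes fell adjusted over the list alone. Rsad2 was at 12.2 ± 2.57 against 34.0 ± 13.4 CPM (-1.48 ± 0.32, adjusted p = 0.720), and the decidual median turned to 0.07 without PNA normal-diet mouse 1. The T cell list lost its call with only the 2 groups fitted (-1.65) and without PNA normal-diet mouse 4 (-0.60). The interaction was negative for interferon (27 of 28, -1.81, 8.05e-15, and adjusted p = 0.818) and decidual genes (22 of 26, -3.72, or -2.95 without genes near 0 counts, 0.00150, and adjusted p = 0.876). It was positive for mesothelium (9 of 10, 2.90, 2.85e-06, and adjusted p = 0.818 with an estimated correlation). In total 3 interferon and 14 decidual genes were negative and 7 mesothelium genes positive adjusted over the list alone. The decidual call was lost without PNA normal-diet mouse 1 (-0.92) or control high-fat mouse 2 (-2.26). For diet edgeR called 0 genes in controls (844 at unadjusted p under 0.05, 16 by DESeq2), 0 in PNA mice (1196 and 15) and 0 in the interaction (1854 and 21). In controls the adipocyte median was -1.30 without control normal-diet mouse 1 and -3.61 without control high-fat mouse 4, and the endothelial median in PNA mice -0.31 without PNA normal-diet mouse 1.

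In placenta, PNA against control mice on normal diet asked how the pregnancy of exposed females differed at E16.5 (4 against 3 mice). Inflammatory cytokine and chemokine genes stood higher in 23 of 24 with a median of 2.54 (camera adjusted p = 6.27e-12, and adjusted p = 0.814 with an estimated correlation), and 16 rose adjusted over the list alone. Neutrophil (14 of 15, 2.90, 4.68e-07), interferon (25 of 27, 0.54, 9.99e-10) and macrophage genes (16 of 18, 0.77, 0.00103) stood higher as well, at adjusted p = 0.814 with an estimated correlation, or adjusted p = 0.893 for macrophages. Of those lists 3 neutrophil, 8 interferon and 0 macrophage genes rose adjusted over the list alone. Examples were the cytokine gene Il1a at 22.9 ± 21.6 against 3.46 ± 1.87 CPM (2.72 ± 0.82) and the chemokine gene Ccl3 at 23.9 ± 25.7 against 0.160 ± 0.153 CPM (7.16 ± 2.19). Others were the neutrophil calprotectin gene S100a9 at 53.8 ± 59.3 against 1.63 ± 0.308 CPM (5.04 ± 1.73) and Stat1, a mediator of interferon signals, at 30.5 ± 6.04 against 18.5 ± 1.25 CPM (0.72 ± 0.16). All 4 had adjusted p = 0.769, the first 3 were above the control mean in 3 of 4 PNA placentas, and Stat1 in 4 of 4. The cytokine score, the mean log2 CPM of the list, was 4.32, 3.98, 1.60 and 0.65 in the PNA placentas and 0.42 to 0.71 in the controls. Markers of yolk sac varied within groups, with scores of 0.27 to 7.25 in these PNA placentas. EdgeR called 0 of 16405 genes (999 at unadjusted p under 0.05, 26 by DESeq2).

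On high-fat diet, PNA placentas (n = 4 per group) stood higher in endothelial genes (15 of 15, 0.30, camera adjusted p = 4.47e-06, and adjusted p = 0.641 with an estimated correlation). They stood lower in yolk sac and liver endoderm (16 of 16, -3.35, 0.000113) and cholesterol synthesis genes (23 of 25, -0.67, 1.81e-05). These 2 lists had adjusted p = 0.663 with an estimated correlation, and 0 genes of any list passed adjusted over the list alone. The cholesterol call was lost without control high-fat mouse 2 (-0.10), and the yolk sac median was 0.04 with the yolk sac score as a covariate. In control placentas the high-fat diet (4 against 3 mice) went with higher interferon (26 of 27, 0.53, 2.93e-11), complement (18 of 18, 1.29, 8.92e-07) and macrophage genes (15 of 18, 0.87, 1.55e-05), at adjusted p = 0.420 with an estimated correlation, or adjusted p = 0.427 for macrophages. Here 1 complement, 1 macrophage and 0 interferon genes rose adjusted over the list alone. Neither comparison called a gene with edgeR: 0 for PNA on high-fat diet (811 at unadjusted p under 0.05, 0 by DESeq2) and 0 for diet in controls (541 and 0). Without control high-fat mouse 2 the yolk sac median was -0.41 and the complement median for diet 0.45. The yolk sac median was -6.43 without PNA high-fat mouse 1 and the endothelial median 0.16 without mouse 2.

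Against controls on normal diet, placentas of PNA mice on high-fat diet (4 against 3 mice), the comparison of exposure and diet combined, stood higher in interferon (27 of 27, 0.69, camera adjusted p = 1.27e-21), macrophage (16 of 18, 1.27, 7.19e-11) and complement genes (14 of 18, 0.75, 7.56e-08). An estimated correlation gave adjusted p = 0.155, adjusted p = 0.155 and adjusted p = 0.200, and 10, 6 and 3 of them rose adjusted over the list alone. Examples were Oasl2, an antiviral gene, at 70.7 ± 16.3 against 36.6 ± 1.51 CPM (0.95 ± 0.24, adjusted p = 1.0) and C1qa, a complement gene of macrophages, at 10.9 ± 5.33 against 3.66 ± 0.593 CPM (1.58 ± 0.46, adjusted p = 1.0), each higher in 4 of 4. Within PNA placentas (n = 4 per group), the high-fat diet went with lower cell cycle (23 of 30, -0.25, 2.76e-05) and cytokine genes (22 of 24, -1.32, 0.00106), both at adjusted p = 0.948 with an estimated correlation. There 0 cell cycle and 0 cytokine genes were lower adjusted over the list alone. The cytokine call was lost with only the 2 groups fitted (-0.99) and without PNA normal-diet mouse 1 (-0.22) or 2 (-0.94). The interaction was negative for cytokine (23 of 24, -1.95, or -1.87 without genes near 0 counts, 0.00162) and interferon genes (25 of 27, -0.44, 0.00165), both at adjusted p = 0.913 with an estimated correlation and with 0 adjusted over the list alone. EdgeR called 0 genes for the combined comparison (390 at unadjusted p under 0.05, 0 by DESeq2), 0 for diet in PNA mice (1206 and 1) and 0 in the interaction (874 and 0). The cytokine interaction was lost without PNA normal-diet mouse 1 (-0.92) and the interferon interaction without PNA high-fat mouse 4 (-0.29). The complement median was 1.28 without control normal-diet mouse 2.

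**Figure D4:**
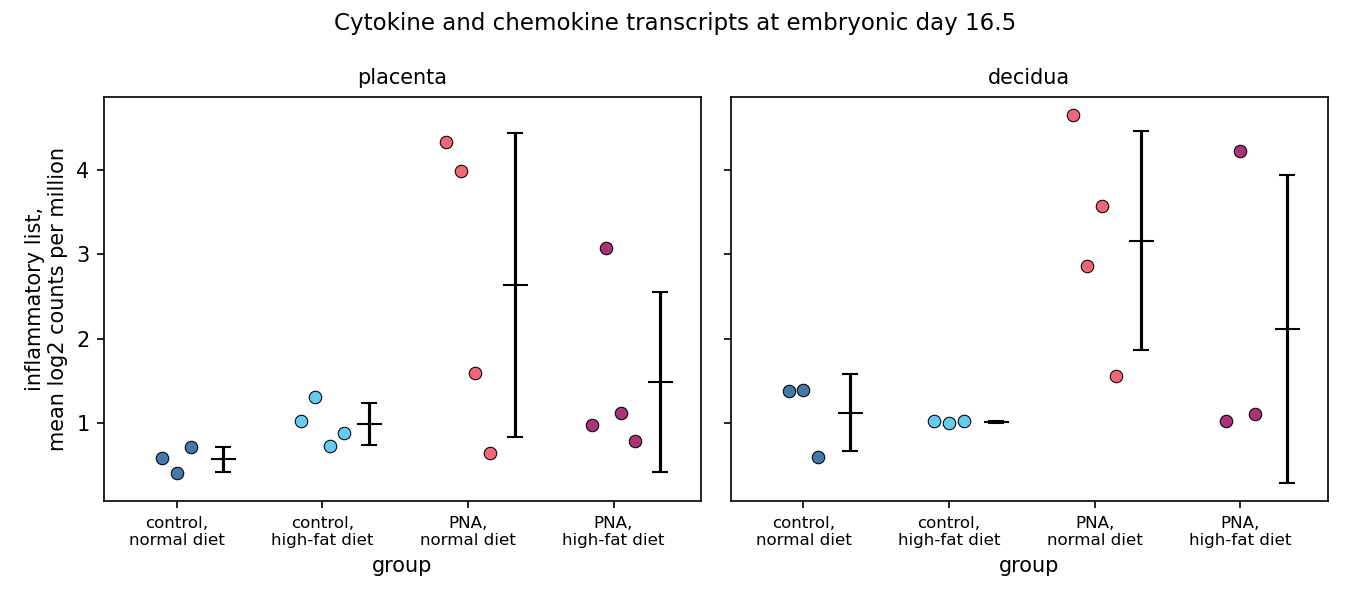
Mean log2 CPM of the inflammatory cytokine and chemokine list in each placenta and decidua at E16.5, with bars for the mean ± SD of 3 or 4 mice per group. Placentas of PNA mice on normal diet averaged 2.64 ± 1.8 and those of their controls 0.57 ± 0.15.

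In decidua, PNA mice on normal diet (4 against 3 mice) stood higher in inflammatory cytokine genes (24 of 26, 1.75, camera adjusted p = 5.82e-12) and immediate early genes of the acute cell response (18 of 20, 0.60, 5.49e-06), both at adjusted p = 0.745 with an estimated correlation. So did neutrophil (11 of 12, 3.77, 0.000146) and estrogen-responsive genes (18 of 19, 2.93, 0.000146). These had adjusted p = 0.849 with an estimated correlation, and 11 cytokine genes and 0 of the other lists rose adjusted over the list alone. Examples were the cytokine gene Il1b at 63.0 ± 94.3 against 0.906 ± 0.944 CPM (6.11 ± 2.01, higher in 3 of 4) and the lipocalin gene Lcn2, made by neutrophils and by estrogen-stimulated epithelium, at 365 ± 281 against 5.91 ± 5.22 CPM (5.95 ± 2.39, higher in 4 of 4), both at adjusted p = 0.999. The cytokine score was 4.65, 2.86, 3.57 and 1.56 in the PNA deciduas and 0.60 to 1.39 in the control deciduas of both diets. Smooth muscle scores were 3.81, 2.75, 2.67 and 7.62 log2 CPM in the PNA and 6.19, 2.61 and 2.60 in the control deciduas. The trophoblast gene Tpbpa was at 12209, 3222, 1667 and 655 CPM in the PNA and at 8665 to 11816 CPM in the control deciduas. The decidua of PNA normal-diet mouse 1 also stood apart in Esr1 (3.71 log2 CPM) and Pgr (3.20 log2 CPM). The estrogen-responsive call was lost without PNA normal-diet mouse 4 (1.42) and with a trophoblast score as covariate (1.95). On high-fat diet (3 against 3 mice), cytokine genes stood higher (24 of 26, 1.43, 0.000479) and erythroid genes lower (11 of 11, -2.03, 0.000479), both at adjusted p = 0.862 with an estimated correlation and with 0 adjusted over the list alone. The PNA high-fat mouse 2 decidua had a smooth muscle score of 6.92 log2 CPM, against 2.59 to 2.99 in the other 5 libraries, and 1109.7 CPM of the lactoferrin gene Ltf, against 0.154 to 29.6. The cytokine call was lost without PNA high-fat mouse 2 (-0.03) and with the trophoblast score (0.96), and the erythroid call without control high-fat mouse 3 (-0.69). EdgeR called 0 of 16146 genes on normal diet (727 at unadjusted p under 0.05, 20 by DESeq2) and 0 on high-fat diet (286 and 1). On normal diet the medians without PNA mouse 1 were 0.39 (immediate early), 1.82 (neutrophil) and 1.66 (estrogen-responsive), the last 1.53 without PNA mouse 3. On high-fat diet the erythroid median was -3.55 without PNA mouse 2 and the cytokine median 2.22 without PNA mouse 1.

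In control deciduas (3 against 3 mice), the high-fat diet went with lower mitochondrially encoded transcripts (12 of 12, -0.65, camera adjusted p = 3.59e-06) and uterine natural killer genes (16 of 16, -1.89, 0.0170), both at adjusted p = 0.925 with an estimated correlation; adjusted over the list alone 1 mitochondrial and 0 natural killer genes fell. The cytochrome oxidase gene mt-Co2 was an example at 21.8 ± 1.85 against 45.3 ± 14.8 CPM (-1.06 ± 0.26, adjusted p = 0.926, lower in 3 of 3). The natural killer call was lost without control normal-diet mouse 1 (0.18) or control high-fat mouse 2 (-1.84), and the mitochondrial call without the libraries that stand apart (-0.21). In PNA deciduas (3 against 4 mice) interferon (27 of 28, -0.44, 7.81e-08) and erythroid genes (11 of 11, -2.31, 0.00124) stood lower on high-fat diet, both at adjusted p = 0.688 with an estimated correlation and with 0 adjusted over the list alone. The erythroid call was lost without PNA normal-diet mouse 1 (-0.27) or PNA high-fat mouse 1 (-1.96), and the interferon call without PNA high-fat mouse 4 (-0.16) and with the trophoblast score (-0.14). PNA mice on high-fat diet against controls on normal diet (3 against 3 mice) stood higher in cytokine (25 of 26, 1.31, 4.92e-07, and adjusted p = 0.916 with an estimated correlation) and lower in mitochondrial transcripts (12 of 12, -0.32, 5.21e-05, and adjusted p = 0.942), with 0 of either adjusted over the list alone. The cytokine call was lost without PNA high-fat mouse 2 (-0.45), and the mitochondrial call without control normal-diet mouse 1 (0.10) or PNA high-fat mouse 4 (-0.15); its median was -0.54 or -0.50 without control normal-diet mouse 2 or 3. The interaction was negative for erythroid genes (11 of 11, -3.87, 0.00107), at adjusted p = 0.988 with an estimated correlation and with 0 adjusted over the list alone. This call was lost without PNA normal-diet mouse 1 (-1.61). In decidua edgeR called 0 genes for diet in controls (602 at unadjusted p under 0.05, 0 by DESeq2), 0 for diet in PNA mice (327 and 5), 0 for the combined comparison (106 and 1) and 0 in the interaction (663 and 15). Ar, Esr1 and Pgr passed in no placental or decidual comparison, and the smallest of their adjusted p-values was 0.755. The mitochondrial median for diet was -0.18 without control normal-diet mouse 1, and the erythroid median for diet in PNA mice -4.08 without PNA high-fat mouse 2. Smooth muscle scores were 6.19 and 6.92 log2 CPM in control normal-diet mouse 1 and PNA high-fat mouse 2 and at most 2.99 in the other deciduas of these groups and of controls on high-fat diet.

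The authors' deposited tables of the same comparisons held adjusted p-values under 0.05 for 3954 genes in PNA against control uteri on high-fat diet at the window of implantation, with Fbxo32 among them, and for 40 on normal diet. In the stimulated horn the authors' deposited tables held 9425 such genes for PNA on high-fat diet, 7394 of them among the 7615 called here, and 397 on normal diet. For the horn response they held 7257 in controls on normal diet (5988 shared with the 6694 called here), 5522 in controls on high-fat diet (4550 shared with the 5770), 0 in PNA mice on normal diet and 3 on high-fat diet.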

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

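Of the tests weighed here, carry-over into the unstimulated horn of control high-fat mouse 2, gene length for the collagen list as a percentage kept, GC content and the splits of the samples were set out before their results were seen; all others were chosen after. Of 204 group values examined, 28 had a library far from the others, where chance gives about 1 in 20. A split stands for another division of the same libraries into groups of the same sizes. Bracketed ranges are 95% intervals from resampling genes 2000 times and hold no spread between mice. What rests on them covers these mice only.

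Decidual transcripts were high in 2 unstimulated horns. In the library labelled unstimulated, PNA normal-diet mouse 1, log2 CPM was 14.92 for Prl8a2 (next -1.60), the decidual score 8.59 (next 4.35) and Ar 5.44 (next 6.54); in control high-fat mouse 2 the score was 7.45. Carry-over of RNA from the other horn of PNA mouse 1 is argued against, since genes of stimulated horns had a median log2 ratio of unstimulated over stimulated CPM of 10.1 (8.72 to 10.4), higher in the unstimulated library for 30 of 32. An exchange of its horn labels may be an explanation: its response across genes had a slope of -1.05 on the control response, against 0.397 to 1.61 in the 8 control mice. For control high-fat mouse 2, carry-over cannot be told apart from a response of the untreated horn, as the ratios spread by an interquartile range of 2.11 (1.22 to 3.21), and an effect of PNA or diet stays open and untested.

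At the window of implantation Ar, Esr1, collagen and endothelial transcripts were low in PNA mice on high-fat diet. GC content is argued against, with 100.7% of the collagen median kept after its trend was removed, and so is library size, with totals of 20.005 to 23.5 M (mega) counts that overlapped the 20.5 to 25.4 M of controls. Gene length may account for Esr1, which moved to 0.052 ± 0.128 (SE) without the trend. Length as the whole cause is argued against for the collagens, whose median of -0.83 (-1.07 to -0.42) kept 77.2% (56.7 to 113) and the list's call; how much of it length made, and whether length made the change of Ar (-0.87 ± 0.25 after, -1.31 ± 0.41 before, not called in either), cannot be told apart from a change in the tissue, since the correction left part of each and the spreads are wide. PNA on high-fat diet itself stays open and untested.

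In placenta inflammatory and neutrophil transcripts were high in PNA mice on normal diet. Yolk sac in the sample is argued against, with 100.1% (94.7 to 101) of the inflammatory median kept with its score as covariate. The decidual score left 98.3% (83.6 to 108) but measures amount, so inflamed decidua in equal amounts stays open. The erythroid score left 88% (62.6 to 95.3), too wide a range to decide. It holds erythroid genes only and cannot judge white cells, so blood stays open. An effect of PNA stays open and untested.

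For PNA on high-fat diet in stimulated horns the real count (7615 genes, highest other 0) was reached in 1 of 35 splits. The count for PNA on high-fat diet at the window of implantation (1, highest other 0) was reached by the same share, the smallest possible. With 35 comparisons made, that share alone cannot exclude chance in either. The margin was 7615 genes in stimulated horns and 1 gene at the window of implantation. The horn responses of controls on normal (6694, highest other 0) and high-fat diet (5770, 5178) were also reached in 1 of 35, but these splits ignore that both horns came from 1 mouse. Only 8 splits part the horns of all 4 mice, too few, with a highest other of 0 on normal diet and of 1806 on high-fat diet, the latter by exchanging mouse 2. In PNA mice the horn response was 0, against 3384 on exchanging mouse 1 on normal diet and 0 on high-fat diet.

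The other counts of genes were 0, which every split reaches (35 of 35, or 30 of 30 for interactions and differences), so they say nothing about chance. The highest other split gave, at the window of implantation, 4 for PNA on normal diet, 8985 for diet in PNA mice and 0 for diet in controls and the interaction. It gave 0 in unstimulated horns, and in stimulated horns 4 for PNA on normal diet, 1853 and 239 for diet in controls and PNA mice and 0 for the interaction. Placenta gave 1 for PNA on high-fat diet, 168 for diet in PNA mice, 12 for the interaction and 0 elsewhere, and decidua 18 for PNA on normal diet, 470 for diet in PNA mice and 511 for the interaction. The horn response gave 3384 and 1 in PNA mice and its differences 1348, 6483, 248 and 158. Splits that call so many genes point to structure among the libraries. In decidua PNA on high-fat diet, diet in controls and the combined comparison had only 10 splits, too few (0 genes, highest other 0).

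Chance cannot be excluded for any count of lists with over 10 splits (splits as large; real; highest other). At the window of implantation, for PNA on normal and high-fat diet, diet in controls and in PNA mice, and the interaction, these were 29 of 35 (8; 20), 27 of 35 (6; 11), 24 of 35 (12; 17), 20 of 35 (7; 13) and 16 of 30 (11; 16). In unstimulated horns they were 29 of 35 (11; 17), 30 of 35 (6; 14), 17 of 35 (10; 15), 33 of 35 (9; 19) and 18 of 30 (11; 21), and in stimulated horns 20 of 35 (11; 20), 19 of 35 (9; 19), 29 of 35 (9; 15), 29 of 35 (9; 18) and 30 of 30 (4; 20). Placenta had 22 of 35 (8; 16), 8 of 35 (13; 16), 3 of 35 (11; 12), 34 of 35 (4; 20), 5 of 35 (13; 17) for the combined comparison and 19 of 30 (7; 16). Decidua had 12 of 35 (13; 17) for PNA on normal diet, 21 of 35 (11; 21) for diet in PNA mice and 21 of 30 (10; 20) for the interaction, and its other comparisons too few splits, 10 of 10 (7; 19), 9 of 10 (5; 15) and 10 of 10 (8; 17). The horn response had 16 of 35 (13; 23), 20 of 35 (8; 13), 29 of 35 (10; 19) and 13 of 35 (11; 19), and its differences 11 of 30 (13; 18), 26 of 30 (7; 13), 22 of 30 (10; 17) and 24 of 30 (10; 17).

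Other libraries far from their group, as log2 CPM or a mean of it, were at the window of implantation PNA high-fat mouse 1 (Ar 6.25), control high-fat mouse 4 (squamous epithelium 2.47), control normal-diet mouse 4 (Ar 6.04) and 3 (Esr1 8.08, neutrophils 3.35, squamous epithelium 7.30). Stimulated horns had control normal-diet mouse 3 (Ar 3.91), 4 (inflammatory genes 3.20) and 2 (squamous epithelium 2.86), control high-fat mouse 4 (Prl8a2 5.55, decidual markers 5.99, neutrophils 1.36, adipocytes 0.89) and 1 (yolk sac 1.06), and PNA high-fat mouse 3 (yolk sac -0.033). Unstimulated horns had PNA high-fat mouse 3 (Prl8a2 -2.16, total 23.6 M counts) and 4 (neutrophils 4.16). Placenta had control high-fat mouse 4 (total 15.2 M counts), PNA high-fat mouse 2 (Ar -3.10, inflammatory genes 3.07, neutrophils 3.69) and 1 (yolk sac 6.07), and decidua had PNA normal-diet mouse 1 (Esr1 3.71, Pgr 3.20).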

How the results depend on the processing

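The gene length correction, the yolk sac covariate and the fits without named libraries, listed above, were chosen after the results were seen. The other alternatives were planned. Size factors in place of TMM changed no call of 108 gene and 137 list results (some, among them ones that moved by over 1.5 times without 1 library, are not described) and no count by over 1.5 times. No filter on low counts ended 2 gene calls (Tfpi2 at 3.87 and Cdh3 at 3.74 in controls on high-fat diet, adjusted p = 0.0666 and 0.0553) and added 1 list call. Where a value changed, the cause was not tested unless stated. The covariate for fetal sex was not run.

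DESeq2 called 13 more of 107 genes tested and ended no call. It gave at the window of implantation 122 genes (0 by edgeR) for PNA on normal diet, 2190 (1) on high-fat diet, 1 (0) for diet in controls and 14 (0) in PNA mice. In unstimulated horns it gave 10, 19, 16, 15 and 21 for the interaction (0 each). In stimulated horns it gave 1369 for PNA on normal diet, 1 for diet in controls, 624 in PNA mice and 200 for the interaction (0 each). The horn response gave 5 and 30 in PNA mice on normal and high-fat diet, and its differences 1310, 1489, 35 and 28 (0 each). It gave in placenta 26 for PNA on normal diet and 1 for diet in PNA mice, and in decidua 20, 1 for PNA on high-fat diet, 5 for diet in PNA mice, 1 for the combined comparison and 15 for the interaction (0 each). In the other 9 comparisons DESeq2 and edgeR counts lay within 1.5 times.

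Camera with an estimated correlation called 0 lists in each fit, against 44 at the window of implantation, 47 in unstimulated and 42 in stimulated horns, 56 in placenta, 54 in decidua and 82 for the horn responses, 0 against 325 in all; this ended all 136 list calls tested. With only the 2 groups fitted, which leaves fewer libraries, PNA on high-fat diet at the window of implantation gave 0 and the horn response of controls on high-fat diet 2951 (5770), with 3 gene and 8 list calls lost. The length correction gave 562 for PNA on high-fat diet at the window of implantation, turned Esr1 to 0.052, added the calls of Lox and C1ra and ended none of 19 list calls.

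With the replicate number or the mouse as a block, PNA on high-fat diet at the window of implantation gave 0 (1), where Fbxo32 stayed at -1.38 (adjusted p = 0.0606), and Prl8a2 in stimulated horns of PNA mice on normal diet turned to 0.26 (adjusted p = 0.973). In the horn response, where mice pair the libraries, blocking moved the counts from 6694 to 4834 and from 5770 to 4538. This ended the calls of Prl8a2 (13.23) and Foxj1 (-4.00) on normal diet and of the estrogen-responsive list on high-fat diet, with 3 of 108 gene and 3 of 137 list calls lost in all and no other call changed. In single settings same-numbered libraries had median correlations across genes of -0.018 to -0.145.

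Leaving out PNA normal-diet mouse 1 moved the decidual list in unstimulated horns to a median of 0.024 for PNA on normal diet, where the test's direction turned and the median's sign did not, and turned it to 0.070 for diet in PNA mice. It gave 479 genes (0) for diet in stimulated PNA horns and 1 (0) for their interaction. Without control high-fat mouse 2 the difference of the horn response between PNA and control on high-fat diet was 2815 (0). The yolk sac covariate turned the yolk sac list in placenta to 0.038, which it was built from. Without the deciduas that stand apart the natural killer list turned to 0.19 for diet in controls. List calls ended numbered 6 of 15 without the libraries high in squamous markers, 4 of 26 without control high-fat mouse 2, 4 of 34 without PNA normal-diet mouse 1 and 5 of 14 without the deciduas, counting those that turned, 3 of 14 with the trophoblast and 1 of 20 with the yolk sac covariate.

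Leaving out each library in turn gave 0 to 1 genes for PNA on normal diet at the window of implantation. On high-fat diet it gave 0 to 5138 (5138 without PNA mouse 1, 1 without control mouse 1). Stimulated horns gave 0 to 1506 for PNA on normal diet (1506 without PNA mouse 4). They gave 0 to 479 for diet in PNA mice and 0 to 1 for the interaction. The horn response gave 3585 to 6457 in controls on normal diet (3585 without stimulated mouse 3). On high-fat diet it gave 2389 to 8530 (2389 without unstimulated mouse 1). Its differences gave 0 to 1235 on normal diet and 0 to 4254 on high-fat diet. Prl8a2 for PNA on normal diet in stimulated horns ranged from -1.74 to 1.38. The decidual list in unstimulated horns gave 0.024 to 3.05 for PNA on normal diet and -2.76 to 0.0700 for diet in PNA mice. The mitochondrial list in decidua gave -0.54 to 0.10 for the combined comparison. Of 869 gene values 27 lost and 12 gained a call, and of 1275 list values 64 lost a call, 3 more lost it and turned, and 3 gained one. Genes with 3 counts or fewer in a group gave only bounded ratios, and other depths were not tried.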

Other observations

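The values in this part were chosen after they were seen, and no tests beyond those of the same lists in the account above were run. Markers of the mesothelium, the lining of the peritoneal surface, were scored in both horns. In stimulated horns its score was 2.25 ± 0.85 in control normal-diet, 2.56 ± 0.37 in control high-fat, 4.81 ± 1.54 in PNA normal-diet and 4.22 ± 0.83 in PNA high-fat mice (mean log2 CPM, SD, n = 4 each). In unstimulated horns it was 2.08 ± 0.89 in control high-fat, 3.99 ± 1.0 in control normal-diet, 3.57 ± 0.32 in PNA normal-diet and 3.96 ± 0.71 in PNA high-fat mice.

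Placentas and deciduas of the same group and number had inflammatory scores, placenta first, of 4.32 and 4.65, 3.98 and 2.86, 1.60 and 3.57, and 0.65 and 1.56 for PNA normal-diet mice 1 to 4. For PNA high-fat mice 1, 2 and 4 they were 0.98 and 1.03, 3.07 and 4.22, and 0.79 and 1.10. Per the labels each pair shares a code, and whether it marks the same dam is not stated.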
